A study of Mus musculus with 83 samples.

How the data were processed

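Of the 83 samples of the series, 6 had processed files that were used here: RNA of cultured brown preadipocytes at days -3, 0, 2 and 7, RNA of brown adipose tissue, and 3T3-L1 input DNA. The other 77, which are ChIP-seq, FAIRE-seq and input libraries, were not analysed here. Samples were grouped by their titles, each group holding 1 library.

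The culture values are gene-level FPKM, fragments scaled for transcript length and mapped fragments, as the authors deposited them by gene symbol. Each gene listed had a value above 1 in at least 1 of the 4 libraries, since the smallest maximum was 1.00125. A missing gene cannot be taken as low: Pnpla2, for one, has no value in the culture tables and is at 652 RPKM in the tissue, and why genes are missing is not given in the sources used here. List counts cover only the members with values. Per the submitters' processing notes, the tools were CASAVA 1.8.2, SICER, TopHat2 2.0.10 and Cufflinks 1.0.3, with build mm9; which tool made which file and which annotation was used is not given in the sources used here. The tissue values are RPKM, reads scaled for transcript length and mapped reads, as the authors deposited them for 29082 RefSeq transcripts, for which the notes name CASAVA 1.8.2 and mm9. The input file, as deposited, lists 1 aligned read per line with a mapping score from 4 to 203 whose meaning is not stated; 99.4% of its reads span 50 bases. RNA was poly(A)-selected from total RNA, per the labels' protocols.

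Depth was looked for in the low values. Among culture genes below 0.3 FPKM in both libraries of a pair, at most 4.65% shared 1 ratio, so read depth was not recovered and no interval is given for them. For the tissue, the lengths of chemosensory receptor genes in a table of assembly GRCm38.p6, another build than mm9, were used for an estimate. All 31 such transcripts came out as whole numbers of reads within 0.01 of a read when 1 read on 1 kb was worth 0.187 RPKM, and 3 such reads are worth 0.561 RPKM. This floor and the Poisson intervals of the input cover counting error only.

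Everything else was computed from these values with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Differences are of log2(value + 1), a scale that understates differences of genes with low values. A gene was counted as higher or lower when this differed by at least 1 (2-fold on that scale), among genes whose larger value was at least 1. Values were used as deposited. The median-ratio factors of the 4 libraries differed from 1 by at most 1.35%. These are rules of size for 2 libraries, not tests of the conditions.

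A total of 37 gene lists (pathways, complexes and cell type markers) were fixed before the data were examined, as were the comparisons, the alternatives except those said to be added, and the rule for the genes named. A list stood apart when its median difference lay outside the central 95% of 10000 random lists of the same size, matched in 20 bins of mean expression. This describes the libraries. Lists with fewer than 5 compared members got no percentile. Between 33 and 34 lists were ranked per step, of which about 1.65 to 1.70 would stand apart by chance if their genes were unrelated. Those that did numbered 10, 18, 19 and 19 in the order of the 4 steps, day -3 to day 7 being the last. Listed genes may vary together, lists share members and steps share libraries, so more lists than that may stand apart by chance.

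The genes named were, for each step, the 6 with the largest difference each way among genes with a larger value of at least 10. So were the 3 members with the largest difference in the direction of each list that stood apart. So were the genes of the profiled factors, Mll3, and members of the adipocyte, late adipogenic factor and brown fat lists. The tissue comparison used the same rule with rank differences. Some genes that the rule takes are not reported here. Mki67, Top2a in culture, Cdk1 over time, Cdkn1b, Cdkn2c, Ebf1, Ldha, Cd68, Cd14, Cd74, Lck, Aldh1a7, Gapdh, Ppia, Rpl10a, Rpl28, Pnpla2 and the muscle, endothelial, hemoglobin and macrophage genes of the tissue were chosen after their values were seen.

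Tissue transcripts were matched to symbols by RefSeq accession in the same table of assembly GRCm38.p6, used for names and for those lengths; 28436 of 29082 (97.8%) matched 1 symbol, each gene took its highest transcript, and 10995 culture genes (98.7%) had a tissue value. Ranks were compared within each library over genes with a value of at least 1 in either. For the input, reads were kept once per chromosome, start and strand, and divided by the span of each chromosome in the file. The segment rule of 3 adjacent 100 kb bins at 3 times the median was set after the values were seen.

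The size rule, list percentiles and segment rule were tested on simulated data. In a simulated day 0 library made from 9987 compared genes of day -3 with noise of SD 0.25, 100% of genes given a log2 change of 2 and 98% of those given 1.5 were called, and 0 of the other 9787. Of 100 random lists 5 stood apart, and of 100 lists shifted by 0.5 all did. The noise was set by assumption, since single libraries give no measure of it, and the simulated lists held unrelated genes. These rates show that the rules work as written, and not how often they err in the real libraries. The alternatives tried were pseudocounts of 0.1 and 5, other minimum values, a 3-fold rule, 2 rescalings, unmatched random lists, other filters for the tissue, and other read filters for the input.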

Results

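The series followed adipogenesis of brown preadipocytes, the precursors of heat-producing fat cells, taken from interscapular brown fat of newborn mice and immortalized with the SV40 large T antigen. The cells carried floxed alleles of Pparg. RNA was sequenced at 4 times: day -3, when the cells were proliferating; day 0, when they were confluent and were induced with insulin, T3, IBMX, dexamethasone and indomethacin; day 2, as immature adipocytes; and day 7, as mature adipocytes. Another RNA library came from interscapular brown adipose tissue of mice aged 16 weeks, and a DNA library was the input, sheared chromatin without antibody, of 3T3-L1 white preadipocytes at day 7 of differentiation, as its title and cell type label give it; its growth protocol describes brown preadipocytes instead. Each time or tissue had 1 library, so no difference here has a replicate check and no p-value is given. The chromatin libraries of the series were not analysed here. The 4 culture tables listed 11144 genes, with a median of 12.2, 13.0, 13.2 and 13.4 FPKM at days -3, 0, 2 and 7. The depth of these 4 libraries is unknown. In the tissue library 1 read on 1 kb of transcript was worth an estimated 0.187 RPKM, and the input file held 5064617 reads.

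The study profiled several transcription factors and cofactors on chromatin, and the RNA libraries show when their genes were expressed. Cebpa, a master regulator of adipocyte differentiation, was at 1.12 FPKM at day -3 and 1.15 at day 0, then at 177 at day 2 and 234 at day 7. Pparg, the nuclear receptor that drives adipogenesis, was at 16.8 FPKM at day -3, 7.46 at day 0, 47.1 at day 2 and 185 at day 7. Ebf2, a factor of brown fat precursors, was at 5.32 FPKM at day 0 and 26.2 at day 2, and Cebpb, induced early in adipogenesis, went from 24.9 FPKM at day -3 through 35.3 and 69.2 to 104 at day 7. The genes of the chromatin cofactors stayed in a narrower range. Mll2, a symbol used for both Kmt2b and Kmt2d, was read as Kmt2d, the gene of the H3K4 methyltransferase MLL4, because Wbp7, an older symbol of Kmt2b, is listed separately. It lay between 20.1 FPKM at day 2 and 29.1 at day -3. Mll3 (Kmt2c), whose product has no ChIP library by the sample titles, was at 6.05 FPKM at day -3 and 16.1 at day 7. That is a difference of 1.28 on the log2 scale. Crebbp, which encodes CBP, lay between 15.8 and 17.7 FPKM, and Ep300, which encodes p300, between 30.2 and 33.8. Med1, Ctcf and Polr2a differed by less than 2-fold at each step. Neither the H3K4 methyltransferase complex genes nor the list of acetyltransferase, Mediator, BET and SWI/SNF coactivators stood apart from random gene lists at any step.

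**Figure D1:**
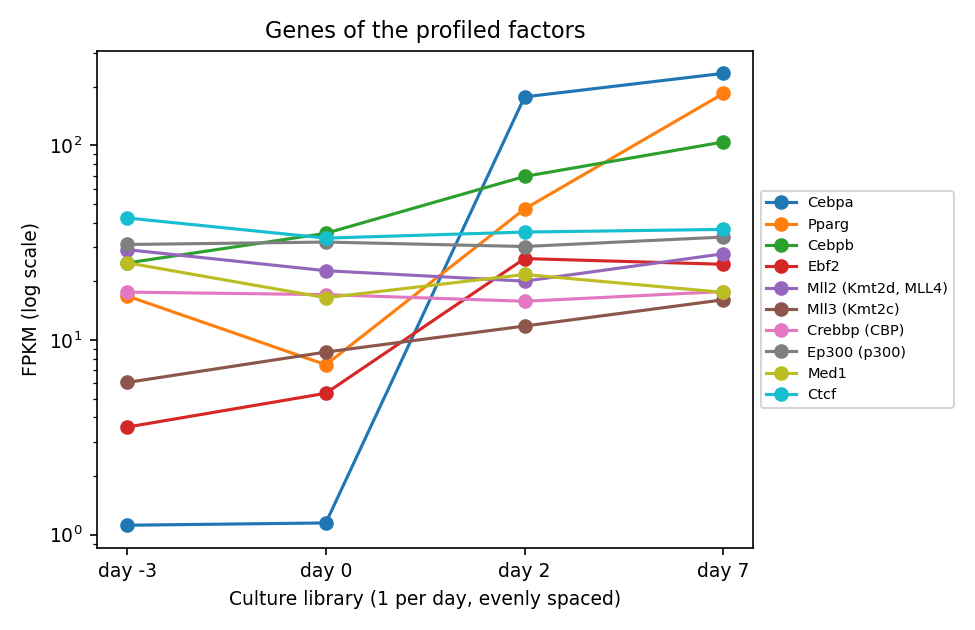
FPKM (log scale) of 10 genes in the 4 culture libraries, 1 point per library, with days evenly spaced and Mll2 read as Kmt2d. The genes encode profiled factors, except Mll3, whose product has no ChIP library by the sample titles. Cebpa goes from 1.15 to 177 FPKM between day 0 and day 2, while Crebbp and Ep300 stay near 17 and 31 FPKM.

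The first comparison asked what differed between proliferating and confluent preadipocytes. Contractile and myofibroblast-type genes were lower at confluence, with 14 of 18 compared members at least 2-fold lower. Acta2, smooth muscle actin and the most abundant transcript of the day -3 library at 6017 FPKM, was at 808 FPKM at day 0. Tagln was at 1367 and 135 FPKM, Cnn1 at 116 and 14.0, and Actg2 at 54.0 and 3.12. The most marked differences downwards also included Ctgf, a matricellular growth factor target, at 1055 and 32.9 FPKM. Fosl1, an AP-1 subunit, was at 76.4 and 3.60 FPKM, Sprr2k at 94.5 and 5.26, and Serpinb2 at 20.1 and 0.449.

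Interferon-responsive genes were higher at day 0, with all 21 compared members at least 2-fold higher and a median log2 difference of 2.51. Oasl2 was at 1.01 FPKM at day -3 and 37.7 at day 0, Isg15, a ubiquitin-like protein, at 3.92 and 67.6, and Irf7, a transcription factor of the interferon response, at 0.987 and 22.7. Of the few immune cell markers in the tables, Cd68 was at 3.403 and 3.315 FPKM, Cd14 at 1.80 and 2.13, Cd74 at 0.519 and 3.21 and Lck at 1.01 and 4.80. Cell cycle inhibitors were higher for 8 of 15 compared genes and lower for 1: Gas1 was at 12.3 and 143 FPKM, Cdkn1c at 4.13 and 21.6 and Gadd45a at 6.19 and 18.8. Extracellular matrix genes went both ways, with 13 of 34 higher and 7 lower. Col3a1, a fibrillar collagen, was at 118 and 1062 FPKM, Dcn, a small proteoglycan, at 3.98 and 44.1, and Col6a2 at 34.9 and 217. Other genes with large differences upwards were Lrrc17 (0.853 and 39.5 FPKM), Dpt (0.624 and 24.6), Rab3il1 (3.42 and 60.7) and Islr (1.09 and 26.8).

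Of the 22 ribosome biogenesis genes on the list 6 have values in the culture tables, and these 6 were at least 2-fold lower at confluence, among them Ncl, which encodes nucleolin, at 237 and 64.4 FPKM, Mybbp1a at 235 and 47.9, and Rrp9 at 78.7 and 12.2. Ribosomal protein genes had a median log2 difference of -0.59, with 5 of 44 at least 2-fold lower. Fatty acid oxidation (median 0.71), cholesterol synthesis (0.54), adipocyte (0.48) and lipogenesis (0.35) lists also stood apart upwards, the last 2 not when genes with low values were kept in or when random lists were unmatched for expression. The matrix list, with a median of 0.08, did not stand apart from unmatched lists either. The mitotic cell cycle list did not, and 0 of its 30 genes differed by 2-fold: Mki67 was at 55.3 FPKM at day -3 and 56.3 at day 0, and Top2a at 136 and 143. In all, 1201 of 10602 compared genes were at least 2-fold higher at day 0 and 576 were lower, which makes 67.6% of the differing genes higher. Rescaling each library to a common total of FPKM made this 2109 higher and 455 lower, 82.3% higher, with the median of all genes shifted by 0.22 on the log2 scale. That total lies above the deposited sums, so it also lessened the weight of the pseudocount and raised the genes compared to 10858. With a pseudocount of 5 it was 55.0%.

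The second comparison covered the first 2 days after induction. Adipocyte markers were higher at day 2 for 25 of 26 compared genes, with a median log2 difference of 2.94. Fabp4, a fatty acid carrier, was at 106 FPKM at day 0 and 4811 at day 2, where it was the most abundant transcript. Lpl, lipoprotein lipase, was at 34.1 and 1842 FPKM, Cd36, a fatty acid transporter, at 0.0657 and 140, Adipoq, the hormone adiponectin, at 0.260 and 142, and Plin1, a lipid droplet protein, at 0.0792 and 30.6. Cav1 was the exception at 292 and 145 FPKM, just inside the 2-fold rule.

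Glucocorticoid-responsive genes were higher for 16 of 19 compared members, with a median of 2.44, after a medium that held dexamethasone. Zbtb16 was at 0.00966 FPKM at day 0 and 30.2 at day 2, Angptl4, an inhibitor of lipoprotein lipase, at 9.33 and 220, and Glul, glutamine synthetase, at 12.3 and 245. Of the late adipogenic transcription factors 8 of 12 compared were higher, including Klf15 at 1.25 and 26.4 FPKM, Ppargc1b at 0.761 and 12.7 and Rxra at 19.5 and 78.2. Of the early factors, Cebpd was at 9.53 and 104 FPKM, Klf9 at 7.99 and 67.4 and Ebf1 at 14.4 and 63.6. Citric acid cycle genes stood apart upwards, with 5 of 19 at least 2-fold higher, 0 lower and a median of 0.58. Pcx, pyruvate carboxylase, was at 8.75 and 132 FPKM and Idh3a at 41.6 and 271, after 117 at day -3. Fatty acid oxidation genes also stood apart upwards, with 6 of 23 higher, 1 lower and a median of 0.61. Among them Acsl1 was at 8.28 and 222 FPKM. Other genes with large differences were Adh1 (0.635 and 523 FPKM), Agt, which encodes angiotensinogen (0.0535 and 241), and Igfbp2 (0.160 and 133). Serpina3n was listed at 0 at day 0 and at 136 FPKM at day 2.

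Cholesterol synthesis genes were lower at day 2 for 13 of 21 members, with Fdps at 39.3 and 7.28 FPKM and Fdft1 at 21.8 and 6.16. The contractile list was lower again for 14 of 18: Vim, the intermediate filament vimentin, was at 2099 FPKM at day 0 and 398 at day 2, and Zyx at 201 and 38.6. Interferon-responsive genes were lower for 18 of 21, Isg15 at 67.6 and 7.26 FPKM. Preadipocyte genes were lower for 11 of 25 and higher for 1. Wnt10b, an inhibitor of adipogenesis, was at 4.90 and 0.173 FPKM, and Gata2 at 9.41 and 2.46. Nerve and Schwann cell markers stood apart downwards too, with 5 of 7 lower and a median of -1.47. Endothelial markers did as well, with 2 of 5 lower. They did not with a pseudocount of 0.1 or 5, with genes of low values kept in, or after rescaling to a common total. Extracellular matrix genes were lower for 15 of 35 and higher for 5, with Tnc at 118 and 19.7 FPKM and Timp1 at 62.9 and 13.7, and glycolysis genes were lower for 5 of 17 and higher for 2, with Pkm2 at 435 and 144. The most marked differences downwards were Sprr1a (75.1 and 0.258 FPKM), Crabp1, a retinoic acid binding protein (283 and 7.11), Tubb2b (21.7 and 0.353) and Dpysl3 (85.0 and 4.70). In all, 662 of 10717 compared genes were higher and 1146 lower.

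The third comparison was between immature and mature adipocytes. Glycolysis genes were higher at day 7 for 15 of 17 members, with a median log2 difference of 2.18. The list was lowest at day 2, with median levels of 39.1, 43.7, 18.6 and 68.8 FPKM at days -3, 0, 2 and 7. Between day -3 and day 7, 9 of 17 were higher and 0 lower, with a median log2 difference of 1.10. Gpi1 was at 79.1 FPKM at day 2 and 1047 at day 7, Aldoa, aldolase A, at 283 and 1985, Pfkp at 13.3 and 130, and Ldha, lactate dehydrogenase A, at 137 and 711. Lipogenesis genes were higher for 17 of 20 with a median of 1.78, led by Thrsp at 0.747 and 78.3 FPKM, Pnpla3 at 0.187 and 23.5 and Acacb at 1.52 and 45.6. Adipocyte markers were higher for 20 of 28 and lower for 2: Cfd, the adipokine adipsin, was at 6.30 and 605 FPKM, Adipoq at 142 and 590 and Slc2a4, the insulin-regulated glucose transporter, at 8.78 and 77.8.

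Of 46 respiratory chain and ATP synthase genes 16 were at least 2-fold higher at day 7, 30 were within 2-fold and 0 were lower, with a median of 0.90; Atp5b was at 793 FPKM at day 2 and 1903 at day 7 and Cox4i1 at 424 and 1012. Of 19 citric acid cycle genes 10 were higher and 9 within 2-fold, among them Cs, citrate synthase, at 127 and 381 FPKM. Brown fat and thermogenesis genes were higher for 11 of 18 and lower for 1. Cox7a1, a muscle and brown fat isoform of a cytochrome c oxidase subunit, was at 1.59 and 132 FPKM, Kcnk3 at 13.6 and 87.9 and Pdk4 at 26.0 and 64.0, while Cidea was listed at 0 at day 2 and at 8.81 FPKM at day 7, and Ucp1, the uncoupling protein of brown fat, was at 0.0357 and 1.22. At the same step pericyte and smooth muscle markers stood apart upwards, with 3 of 5 higher and a median of 1.66: Des was at 0.678 and 12.1 FPKM, Mcam at 7.08 and 35.9 and Cspg4 at 4.21 and 15.5. The median level of this list was 15.5, 15.3, 7.08 and 15.5 FPKM at days -3, 0, 2 and 7. Between day -3 and day 7 it did not stand apart, with 2 of 5 higher and 1 lower. Ndufa4l2 was at 0.911 and 115 FPKM, Apoc1 at 2.54 and 148 and Mb, myoglobin, at 0.631 and 65.1.

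Circadian clock genes were higher for 8 of 18, with Bhlhe40 at 6.59 FPKM at day 2 and 158 at day 7, Dbp at 3.76 and 27.6 and Per3 at 8.19 and 42.2. Cholesterol synthesis genes were higher for 5 of 21, with Insig1 at 23.1 and 82.2 FPKM. Matrix genes were lower for 11 of 35 and higher for 3, Mmp2 at 157 and 39.3 FPKM and Col3a1 at 963 and 256, and chemokine genes stood apart downwards, Cxcl12 being at 248 and 59.97, though not when genes with low values were kept in. Several genes that were high at day 2 were lower at day 7: Igfbp2 was at 133 and 3.04 FPKM, Serpina3n at 136 and 3.69, Prg4 at 33.1 and 0.689, Serpina3m at 23.3 and 0.478, Ctla2a at 28.4 and 1.02 and Frmd5 at 38.9 and 1.82. In all, 1026 of 10666 compared genes were higher and 548 lower.

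Set end to end, day -3 and day 7 differed by at least 2-fold for 2196 genes upwards and 1597 downwards of 10828. Cfd was at 0.225 FPKM at day -3 and 605 at day 7, Adipoq at 0.234 and 590, G0s2, an inhibitor of lipolysis, at 0.166 and 358, C3, complement component 3, at 0.109 and 258, and Scd1, a fatty acid desaturase, at 41.5 and 2495. All 18 contractile genes were at least 2-fold lower, as were 14 of 23 preadipocyte genes, with 2 higher. Ptgs2, a prostaglandin synthase, was at 89.6 and 0.774 FPKM, Csf1 at 467 and 33.3, and Foxc2 at 26.8 and 1.54. In these cells, immortalized with the SV40 large T antigen, the 30 mitotic genes differed by less than 2-fold at each of the 3 consecutive steps. Cdk1 was at 242, 164, 182 and 157 FPKM at days -3, 0, 2 and 7, and Mki67 at 87.0 at day 7, while the inhibitors Cdkn1b (18.5 and 108 FPKM) and Cdkn2c (19.2 and 120) were higher at day 7 than at day -3. The mitotic list stood apart between day 2 and day 7 alone, with a median of 0.26, though not against random lists unmatched for expression.

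**Figure D2:**
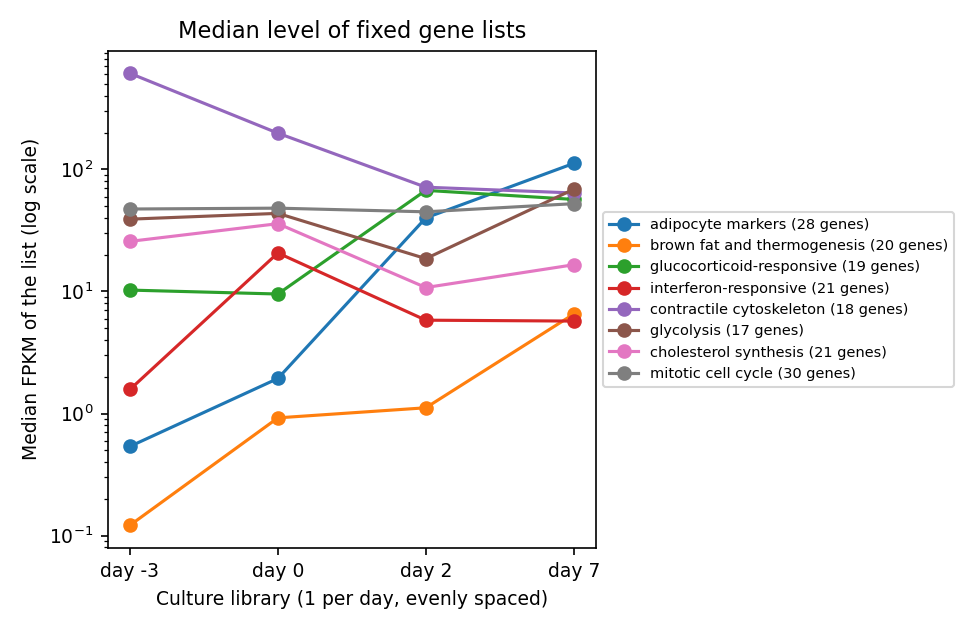
Median FPKM (log scale) of 8 gene lists in the 4 culture libraries, 1 library per day, with days evenly spaced and the number of genes in the legend. The adipocyte median goes from 0.538 FPKM at day -3 to 112 at day 7, the interferon-responsive median peaks at 20.7 at day 0, and the mitotic median lies between 45.0 and 52.4.

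Across the 3 consecutive steps, 3733 of 11144 genes (33.5%) differed by 2-fold at 1 or more. The most common patterns were a difference upwards at the last step alone (539 genes, among them Thrsp and Mb), upwards at the first step alone (539 genes) and downwards at the second step alone (535 genes, among them Tubb2b). Genes flat at the first step, then upwards at day 2 and downwards at day 7, numbered 124, with Adh1, Agt and Aldh1a7 among them. Of the 1201 genes higher at day 0, 360 were then lower at day 2, where independent lists would share 131. Both steps use the same day 0 library, and part of that excess may come from it.

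Gene ranks in brown adipose tissue were closest to those of the day 7 culture. Spearman's rho across genes, which are not independent replicates, was 0.42 at day -3, 0.48 at day 0, 0.57 at day 2 and 0.68 at day 7, the 4 such relations computed. Common adipocyte genes ranked higher in the tissue for 20 of 28, with a median rank difference of 1.49 percentage points that did not stand apart, and their values lay to both sides, set side by side although the culture is in FPKM and the tissue in RPKM. Over all 10269 genes above 0 in both and at least 1 in either, the median log2 ratio of culture to tissue was 1.46. Equal values thus do not mean equal relative levels, and values are given as listed. Tissue genes without a culture value are left out of this median. Each gene in it was above 1 FPKM in some culture library, which may raise the median. Among adipocyte genes whose values lay close, Adipoq was at 590 FPKM in the day 7 culture and 554 RPKM in the tissue. Fabp4 was at 4070 and 5960, Plin1 at 219 and 242 and Plin2 at 208 and 204. Others lay apart: Car3 was at 167 and 1631, Gpd1 at 189 and 1269 and Dgat2 at 84.6 and 532, while Dgat1 was at 330.1 and 49.5 and Fabp5 at 73.2 and 12.4. Cebpa was at 234 and 185. Brown fat genes ranked higher in the tissue, with a median rank difference of 42.8 percentage points, 18 of 20 members being higher. Ucp1 was at 1.22 FPKM in culture and 1015 RPKM in tissue, Cidea, a lipid droplet protein, at 8.81 and 1164, Cox8b at 4.38 and 956, Elovl3, a fatty acid elongase, at 1.91 and 42.4, and Acot11 at 0.374 and 119. Kcnk3, at 87.9 and 92.0, and Cox7a1, at 132 and 300, lay closer.

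Fatty acid oxidation genes ranked higher in the tissue for 23 of 25, Cpt1b, a muscle and brown fat carnitine transferase, being at 5.48 FPKM in culture and 172 RPKM in tissue and Slc25a20 at 16.2 and 165. Of the shared adipocyte genes Pck1, an enzyme of glyceroneogenesis, was at 1.20 and 714. Late adipogenic factors stood apart upwards with a median rank difference of 7.20 and 10 of 16 members higher, among them Ppara (6.52 and 70.3) and Rxrg (3.90 and 11.0). They did not when each gene took the mean of its transcripts or when a value of at least 1 was asked in both tables. Mitotic genes ranked lower in the tissue than in the immortalized culture for all 30 members. Cdk1 and Ccnb2 were at 157 and 89.7 FPKM in culture and listed at 0 in the tissue. Top2a was at 196 FPKM and 0.179 RPKM. The inhibitor Cdkn2a was at 242 FPKM and listed at 0. Matrix genes ranked lower in the tissue, with a median rank difference of -36.8 percentage points and Thbs1 at 82.0 FPKM and 0.483 RPKM, and contractile genes likewise, with a median of -17.4 and Actn1 at 37.7 and 2.60. Psat1, an enzyme of serine synthesis on the white-fat-selective list, was at 141 FPKM and 0.775 RPKM and Agt at 59.6 and 0.508.

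The tissue also held transcripts of other cells. Skeletal muscle genes reached 534 RPKM for Acta1, 237 for Ckm, 205 for Atp2a1 and 155 for Myh4, and muscle also expresses some members of the brown fat and fatty acid oxidation lists, Cpt1b among them. Endothelial genes reached 51.4 RPKM for Cdh5 and 34.4 for Pecam1, the hemoglobin gene Hbb-bs was at 244, and the macrophage gene Lyz2 at 19.6. Gapdh, which has many pseudogenes, was at 17.8 FPKM in the day 7 culture and 0.303 RPKM in the tissue, Ppia at 6.67 and 0.254, and the ribosomal protein genes Rpl10a and Rpl28 at 24.1 and 5.04 FPKM and listed at 0 in the tissue. Genes that every cell uses can thus be listed at or near 0 in the tissue table, so these genes are uncertain. A listing at 0, as for Cdk1, Ccnb2 and Cdkn2a, does not by itself show absence. Ribosomal protein genes of the day 7 culture were as far apart as Rpl35 at 2.38 FPKM and Rpl8 at 863. The culture values of such genes are thus uncertain too.

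**Figure D3:**
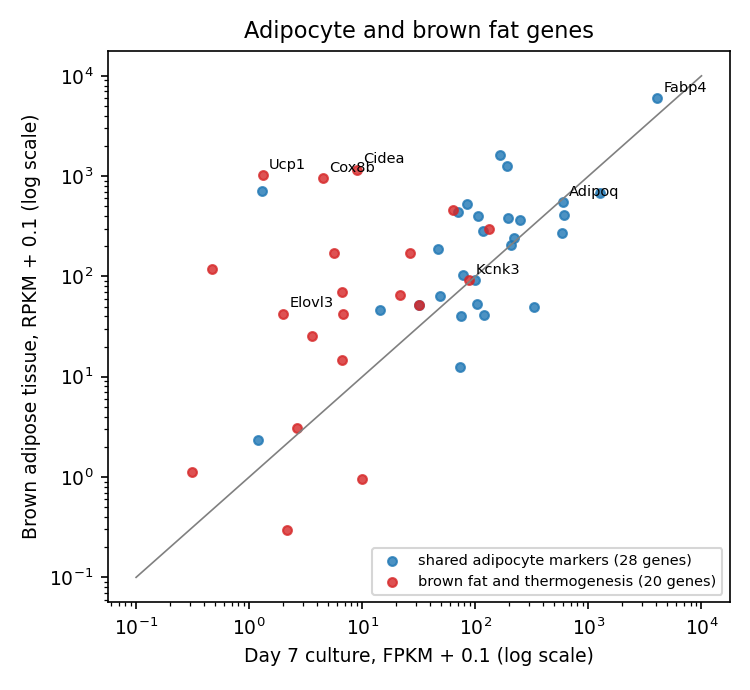
Levels in the day 7 culture (FPKM + 0.1) and in brown adipose tissue (RPKM + 0.1), both on log scales, for shared adipocyte markers (blue) and brown fat genes (red), 1 point per gene and a grey line of equal values. The line takes no account of the median log2 ratio of culture to tissue, 1.46 over all 10269 genes. Ucp1, at 1.22 and 1015, and Cidea, at 8.81 and 1164, lie far above the line, and Fabp4, at 4070 and 5960, lies near it.

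The library labelled as 3T3-L1 input shows how its DNA reads spread over the genome, in mm9 coordinates. Kept once per start and strand, 4901800 reads remained, with a median of 1911 reads per Mb over the 19 autosomes. Relative to that median, chromosome 6 had a density of 1.57 (95% Poisson interval 1.57 to 1.58, counting error only), chromosome 19 of 1.28, chromosome 16 of 1.27, chromosome 7 of 0.675 and chromosome X of 0.597. The lowest autosome was chromosome 7, at 0.773 by the median of 100 kb bins. Chromosome Y held 45 kept reads, a relative density of 0.0097. A segment of chromosome 10 from 116700001 to 117300000, 600 kb in length, held 29827 reads, 26.6 times the autosomal median per 100 kb bin. It was the only segment with 3 or more adjacent bins at 3 times the median. Gene annotation of mm9 was not used here, so no gene is named for it.

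**Figure D4:**
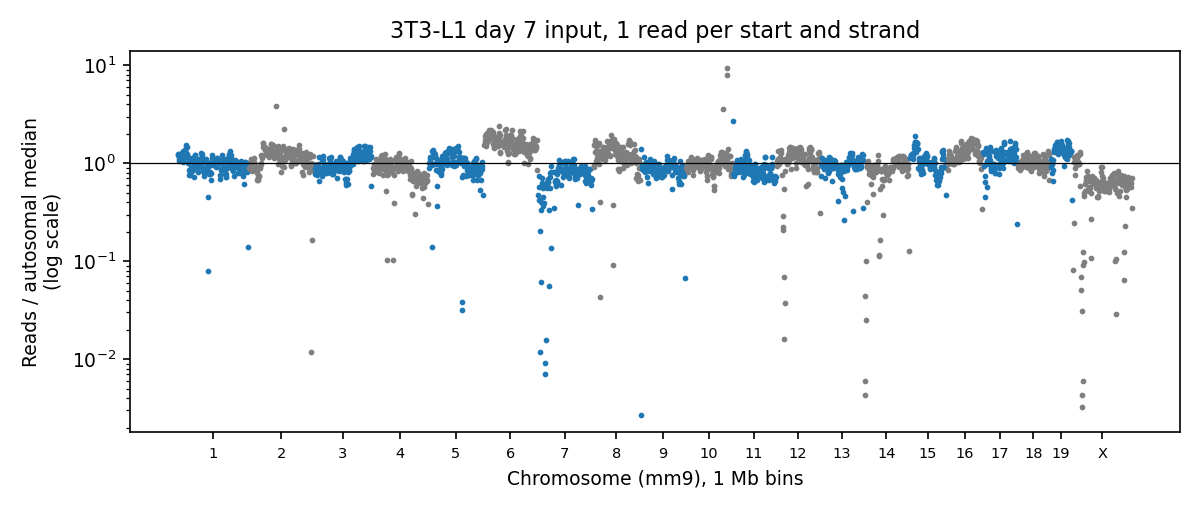
Reads per 1 Mb bin of the 3T3-L1 day 7 input divided by the autosomal median (log scale), along the autosomes and chromosome X in mm9 order, 1 point per bin and colours alternating by chromosome. Chromosome 6 lies above the line at 1, with 97.3% of its bins above the median, and chromosome X lies below it.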

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

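The tests of explanations and the segment rule in this part were chosen after the values were seen; the chromosome densities and the read filters were set before. These results come from the library labelled as 3T3-L1 input, whose growth protocol describes brown preadipocytes. They were flagged as unanalysed data, from a DNA library outside the RNA comparisons, and no matched control was analysed here. Relative to the autosomal median, read density was 1.57 on chromosome 6, 0.675 on chromosome 7, 0.597 on chromosome X and 26.6 on the chromosome 10 segment from 116700001 to 117300000 (mm9).

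Duplicate reads, pile-ups in a few bins and ambiguous read positions were weighed for chromosome 6. With 1 read per start and strand its density stayed at 1.57, above the next highest autosome at 1.28; 97.3% of its 147 bins of 1 Mb lay above the autosomal median; and with reads of the highest mapping score alone it was 1.53. For the chromosome 10 segment, the lowest of its 6 bins held 4.87 times the autosomal median with 1 read per start and strand, and the mean was 25.9 times at the highest mapping score. GC content and mappability stay open, since no mm9 sequence was used here. A gain in copy number in these cells is a candidate explanation, as a hypothesis, and no biological explanation was tested, because no other 3T3-L1 DNA library was analysed here.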

How the results depend on the processing

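The tissue values from the mean of transcripts, the list medians after rescaling to a common total and the patterns without the day 0 library were chosen after seeing the data. No called direction turned for a list under 6 alternatives. For named genes only median-ratio scaling and a pseudocount of 0.1 were run, and neither could turn a called direction. A pseudocount keeps the sign of a difference, and the median-ratio factors differed from 1 by at most 1.35%. The number of list differences that stood apart, 66, was 64 to 67 under 6 alternatives, with 61 to 66 apart on the same side. The adipocyte list at day 0 was lost under 4 of these. In the order day -3 to 0, 0 to 2, 2 to 7 and -3 to 7, a pseudocount of 5 gave 436, 383, 530 and 1243 genes higher and 357, 532, 280 and 1035 lower; a 3-fold rule gave 397, 290, 444 and 1164 higher and 180, 441, 191 and 751 lower, and time patterns with a difference for 1569 genes. Both are stricter by construction. Rescaling to a common total above the deposited sums gave 2109 higher at the first step and 829 lower at the third; it shifted the median by 0.22, 0.02, -0.09 and 0.14. The other counts stayed within 1.5 times. Spearman's rho at days -3, 0, 2 and 7 was 0.48, 0.52, 0.62 and 0.72 without a filter and 0.25, 0.32, 0.43 and 0.57 with at least 5 in either; with at least 1 in both it was 0.45 at day -3 and 0.67 at day 7. Of 16 lists apart in the tissue, 10 stayed with at least 1 in both, where 4 were too small to rank, and 15 with the mean of transcripts. Chromosome 6 was at 1.58 with all reads, 1.62 by the median of 100 kb bins and 1.53 at the highest mapping score; chromosome 7 was at 0.773 by bins and 0.630 at that score, and chromosome X at 0.638 by bins. The cause was not tested where not stated. No paired analysis was possible because each group had 1 library.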

Other observations

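The tests of explanations in this part were chosen after the values were seen. A group of genes was highest at day 2. Aldh1a7 was at 0.574, 1.16, 173 and 22.3 FPKM at days -3, 0, 2 and 7, and Ephx2, an epoxide hydrolase, at 0.659, 1.72, 84.4 and 40.7. Cebpd, an early adipogenic factor, was at 104 FPKM at day 2 and 16.3 at day 7, and Lhx8, on the brown fat list, at 54.2 and 9.85. Others dipped at day 2: Ndrg1 was at 12.8, 59.7, 23.9 and 180 FPKM, and Zfp467 at 1.63, 11.4, 1.77 and 11.4. These genes were chosen after their values were seen, and both patterns rest on the single day 2 library.

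Interferon-responsive genes were highest in the day 0 library, with medians of 1.58, 20.7, 5.82 and 5.72 FPKM at days -3, 0, 2 and 7. Library scaling would move all genes together, but the median log2 difference of all 10602 genes was 0.0625 while the smallest among the 21 interferon-responsive genes was 1.48. Immune cells in the day 0 culture stay open: 6 listed macrophage and lymphocyte markers had a median difference of 0.33, with quartiles of 0.02 and 1.23, too few and too spread to decide. Confluence may be the source, and so may a state of the single day 0 culture, which 1 library cannot separate.

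Brown fat genes were lower in the day 7 culture than in the tissue, with a median log2 ratio of -2.69 (quartiles -4.72 and -1.16, 19 genes), against -0.40 for 27 shared adipocyte genes and 1.46 for all 10269 genes. A scale factor between the tables would move all genes alike and so cannot give these 3 medians. A smaller share of adipocytes in the culture would lower the brown fat and shared adipocyte lists alike if adipocytes alone expressed them. The lists differed by 2.28, with a 95% range from resampling genes of 0.60 to 4.07, which covers the choice of genes and not the libraries. Cav1 was already high before induction and muscle expresses Cpt1b, so that condition is not met and this cause is not excluded. A smaller share may still account for part, since the shared adipocyte genes also lay below the median of all genes. That median covers only genes with culture values, which may raise it. Muscle in the tissue, and the difference between cultured cells and adult tissue, were not tested and stay open.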
